A study of Saccharomyces cerevisiae with 19 samples.

How the data were processed

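The series holds processed files only, and reads were not realigned. Per the authors' notes, reads were trimmed with fastp 0.23.0; the aligner, the counting tool, its strand setting and the annotation version are not given in the sources used here. The deposited count tables hold raw reads per annotated feature made by the authors, 6863 features for WT, ΔPcf11 and Pcf11-AARR and 6943 for WT, Pcf11-OE1 and Pcf11-OE2. WT counts were equal in both tables for all 6863 shared features, and the 80 further features had at most 8 counts. The names of 2 features that a spreadsheet had turned into dates were restored. All 17 chromosome accessions per the file headers are those of assembly R64, 2 features longer than 20000 bases were taken as having faulty coordinates, and 4 had segments on more than 1 chromosome. Of 6437 named features, 4815 (74.8%) overlap another. The library kit is stranded per the labels. In a check added after the data were seen, 0 of 142 features lying inside a feature on the other strand had more reads than the outer feature, in sum or in any library, for pairs of features in 1 segment with a summed count of at least 100. Shuffling the inner counts 1000 times gave 33.4 on average and 24 at least. Of 124 inner features, 66 had a read density of at least 0.5 times that of the outer feature and 58 a lower one, so density alone does not settle the strand setting.

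The deposited RPKM values were made by the authors as counts over feature length and column total, and recomputing them gave relative differences of at most 5.1e-15; they were used for this check alone. The log2 fold changes of the authors' deposited tables, WT over each other strain per the file headers, and their p-values and FDR come from a test the authors do not name. At an FDR of 0.05 and 2-fold they give 1260, 1401, 439, 1634 and 1405 genes for ΔPcf11 and Pcf11-AARR against WT, for these 2 against each other and for Pcf11-OE1 and Pcf11-OE2 against WT, of which 1164, 1311, 402, 1526 and 1305 were tested here and 1163, 1310, 401, 1524 and 1304 called in the same direction. The mapped percent and the percent of reads in 5' UTRs and other regions are values the authors deposited. CLIP peaks were called by the authors for each IP library against its input after removal of duplicates, and the peak height is the highest read depth in a peak as deposited, a signal without scaling. The annotation shares of each peak are the authors' own. Input FPKM values, per kilobase and per 1e6 reads, were made by the authors, with sense and antisense counts per gene.

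Counts were tested with edgeR 4.0.16 in R 4.3.3, with 1 fit for each count table, TMM scaling, filterByExpr, robust quasi-likelihood F tests and Benjamini-Hochberg adjusted p at 0.05, which left 6119 features in each table. Levels are CPM after TMM scaling. Replicates of a strain differed by 38.9 to 390.4 times the chi-square per degree of freedom of counting noise over 15 pairs, with a biological coefficient of variation of 0.133 and 0.144 in the 2 tables. Alternatives changed the scaling, the filter, the groups in the fit, the replicate block and the libraries kept, 1 at a time. The DESeq2 alternative changed the test, scaling and filter together: all 6409 and 6406 features with at least 1 read were fitted, with its own size factors and independent filtering. Gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01 and, as an alternative, with estimated correlations. Of 36 gene lists, 35 were tested, 1 for retrotransposons having matched 0 features. DESeq2 1.42.0 served as an alternative. Overlaps of calls were set beside n1 × n2 / N and beside 20 simulated data sets with no change against the same WT libraries. CLIP peaks were compared with bedtools 2.31.1 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, scipy 1.17.1), and figures drawn with matplotlib 3.10.9. Bound genes had a sense peak in both IP libraries and were set against calls within 10 expression deciles by an exact Cochran-Mantel-Haenszel test. Peak positions were compared with 1000 random draws in the same genes, and 6-mers with random windows of equal length in the same genes by Fisher's exact test.

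Lists, tests and the rule for named genes were chosen before the data were examined. The rule takes PCF11, then the 10 highest and 10 lowest log2 fold changes (5 and 5 in the comparisons without WT) among called genes with a standard name, a mean of at least 10 CPM in the higher group and no overlap between the replicates of the groups. Of each list described it takes up to 4 members, the highest and lowest of those called. For CLIP it takes the 10 highest shared peaks on named genes. Groups of 3 against 3 do not overlap by chance in 10% of genes with no change, and 69.1%, 70.5%, 52.3%, 73.5%, 70.6% and 14.9% of the genes did not overlap in the 6 comparisons in the order of the report, ending with Pcf11-OE2 against Pcf11-OE1. Genes whose lower group held 1 to 3 reads are given as a ratio with its counting interval.

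Same-numbered libraries were checked for pairing: 6 of 18 pairs had a correlation over 0.1, and only Pcf11-AARR with WT had all 3 above it (0.113, 0.184 and 0.371), so the value with a replicate block is given beside that comparison. In a self-test on simulated counts, edgeR recovered 92.5% of genes changed 2-fold in both tables, 56.7% and 46.3% of those changed 1.5-fold, and called 0.288% and 0.220% of unchanged genes. Camera found the planted list and called 0 of 20 random lists in each table. The simulated genes varied independently, so this cannot show how camera at the preset correlation behaves with correlated genes. Other groupings of the real libraries of a comparison called up to 18 lists. They mix both strains on each side and keep part of the difference, so they do not measure false calls. The exact test of bound genes gave an unadjusted p below 0.05 in 10 of 100 random sets drawn by expression and in 6 of 100 drawn evenly, and in 20 of 20 enriched sets, so it is somewhat liberal.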

Results

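Pcf11, a subunit of the complex that cleaves and polyadenylates messenger RNA 3' ends and takes part in ending transcription by RNA polymerase II, was altered in Saccharomyces cerevisiae. Transcripts were measured by RNA sequencing in 5 strains with 3 biological replicates each. Besides WT, the labels give a deletion of the gene (ΔPcf11), a version with 4 conserved residues changed (Pcf11-AARR), and 2 strains that overexpress it (Pcf11-OE1 and Pcf11-OE2). The labels name S288C and CEN.PK2-1C together for every library, state 36 h, and do not say which of the 2 promoter and terminator pairs belongs to which overexpression strain. A further 4 libraries come from CLIP sequencing, which reads RNA crosslinked to a protein, of Flag-tagged Pcf11, with 2 immunoprecipitations (IP) and 2 inputs. Total counts of the 15 RNA-seq libraries were 26211192 to 46296634, and 6248 to 6316 features were detected per library. The authors' mapping table covers 9 libraries, of which 49.9% to 95.3% of the reads mapped. Mapped shares were 88.3% ± 6.14 in WT, 58.4% ± 2.98 in the libraries labelled ΔPcf11 and 69.8% ± 20.9 in Pcf11-AARR (SD, n = 3). The share of assigned reads in 5' UTRs was 0.49% ± 0.053, 0.203% ± 0.012 and 0.127% ± 0.015. The same 3 WT libraries serve all comparisons with WT. Of 142 features lying inside a feature on the other strand, 0 had more reads than the outer feature, where at least 24 had more in each of 1000 draws with the inner counts shuffled. Reads of an inner feature thus appear to count for the outer one too, and values of overlapping genes are uncertain.

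Reads were counted on PCF11 in all 5 strains. In the libraries labelled ΔPcf11, its level was 12.3 ± 0.541 CPM against 15.1 ± 2.09 CPM in WT (SD, n = 3), a log2 fold change of -0.30 ± 0.12 SE with an edgeR adjusted p of 0.0456. Reads on a gene stated to be deleted were thus not missing. Reads of the overlapping gene SIR4, described below, may be part of the levels in both strains. Pcf11-AARR had 20.5 ± 1.24 CPM (log2 fold change 0.45 ± 0.12 against WT, edgeR adjusted p = 0.00604). Pcf11-OE1 reached 578 ± 28.5 CPM, 38.3-fold above WT, and Pcf11-OE2 74.7 ± 11.4 CPM, 4.95-fold above WT (edgeR adjusted p = 1.78e-08 and 7.57e-07). PCF11 (YDR228C) lies on chromosome IV, bases 921441 to 923806, minus strand, of assembly R64, and SIR4, a silencing gene on the other strand, overlaps 666 of its bases, 28.1%. SIR4 counted 37.8 ± 2.12 CPM in WT, 52.8 ± 3.17 in the libraries labelled ΔPcf11, 45.0 ± 1.72 in Pcf11-AARR, 134 ± 4.02 in Pcf11-OE1 and 67.9 ± 5.95 in Pcf11-OE2. Reads of PCF11 over the shared bases may be among these counts, so a change of SIR4 itself cannot be read from them. Exact permutation tests of the log2 CPM gave p = 0.1, two-sided, in each of the 6 comparisons, the smallest that 3 against 3 libraries allow. The call of lower PCF11 in the libraries labelled ΔPcf11 was lost with relative log expression, DESeq2, no filter, the replicate block or only 2 groups in the fit, and without any 1 of the 3 ΔPcf11 libraries or WT replicate 1. Leaving out 1 library gave log2 fold changes from -0.35 to -0.18. The authors' deposited table gives an FDR of 0.0847 for it.

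**Figure D1:**
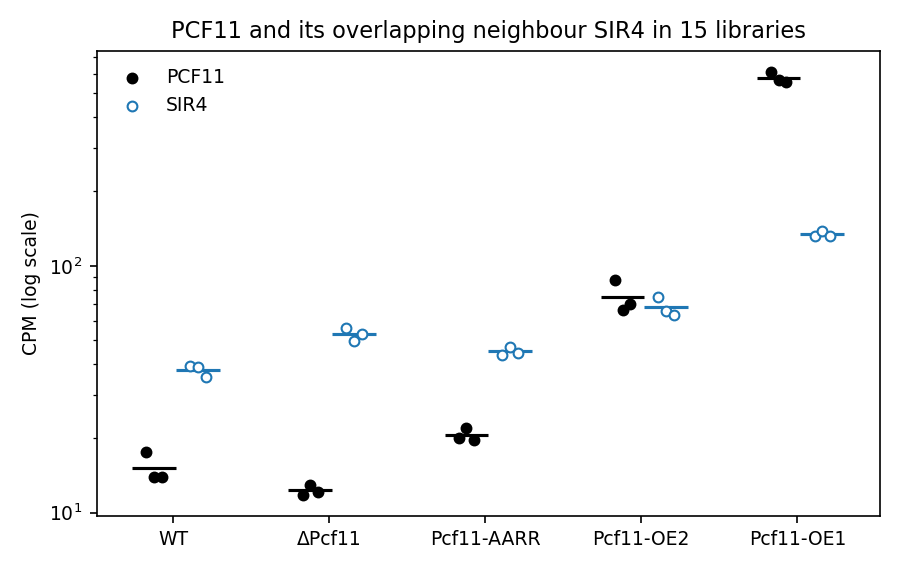
CPM of PCF11 (black) and of SIR4, which overlaps it on the other strand (blue), on a log scale, with 1 point per library and a bar at the mean of the 3 libraries of each strain. PCF11 lies between 11.8 and 21.9 CPM in the 9 libraries of WT, ΔPcf11 and Pcf11-AARR, and between 66.3 and 610.4 CPM in the 6 overexpression libraries.

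The comparison of the libraries labelled ΔPcf11 with WT sets strains that differ in Pcf11 by label. Transcripts of single genes for maltose and asparaginase were far higher, and those of single genes for acetate, ethanol and phosphate far lower, than in WT. The maltase genes MAL12 (chromosome VII, bases 1076599 to 1078774) and MAL32, near-identical copies that share reads, stood at 577 ± 61.1 and 437 ± 61.7 CPM against 3.5 ± 0.382 and 2.75 ± 0.545 CPM in WT (SD, n = 3). The maltose transporter MAL11 (38.1-fold) rose with them. Transcripts of asparaginase II from the ASP3 cluster on chromosome XII, whose copies also share reads, were all but missing in WT. ASP3-2 had 2 reads over the 3 WT libraries, and its level in the libraries labelled ΔPcf11 was 6976 times (95% counting interval 1931 to 57605) the WT level. ASP3-4, with 3 WT reads, was at 838 times (95% counting interval 286 to 4066) that level. Of the genes that fell, ADY2 (log2 fold change -6.63 ± 0.46 SE, 209 ± 127 against 20756 ± 1929 CPM) encodes the acetate transporter, and ADH2 (146 ± 79.5 against 2912 ± 229 CPM) the alcohol dehydrogenase that oxidises ethanol. The sodium-phosphate cotransporter PHO89 (44.6-fold), the sodium pumps ENA1 (28.8-fold) and ENA2 (38.2-fold), which share reads, the ABC transporter PDR18 (66-fold) and the serine and threonine deaminase CHA1 (22.6-fold) fell as well.

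Of the other genes with the largest rises, RDT1 had 2 reads in WT and stood at 471 times (95% counting interval 130.0 to 3891) that level, and ERR3 (62.2-fold), an enolase-related gene with close paralogs, SNO4 (57-fold), of the Hsp31 family, and MFA2 (29.9-fold), which encodes the a-factor pheromone, also rose. MHF2 rose 17.1-fold, but ENT1 overlaps 87.2% of it. The remaining genes with the largest falls were close to 0 CPM in the libraries labelled ΔPcf11: ADH7 (0.0559 ± 0.0327 against 16.7 ± 1.51 CPM), SEO1 (0.0573 ± 0.0607 against 12.8 ± 0.212 CPM), AIF1 (0.0813 ± 0.0512 against 15.5 ± 1.5 CPM) and RDS1 (0.114 ± 0.078 against 14.6 ± 0.399 CPM).

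Cytosolic ribosomal protein and ribosome biogenesis genes rose, and gluconeogenesis and tricarboxylic acid cycle genes fell, as groups. Of the cytosolic ribosomal proteins, 99 of 138 rose and 6 fell (99 and 6 adjusted over the list alone), with a median log2 fold change of 0.71 and RPL43B (8.24-fold) and RPL30 (5.21-fold) at the top. For cytosolic ribosomal proteins, the camera adjusted p was 1.06e-06, and the adjusted p was 0.586 with an estimated correlation. Among ribosome biogenesis genes, 69 of 97 rose and 7 fell (69 and 7 adjusted over the list alone), led by NSR1 (8.78-fold) and DBP2 (5.62-fold). For ribosome biogenesis, the camera adjusted p was 2.30e-05, and the adjusted p was 0.586 with an estimated correlation. Of the genes for gluconeogenesis, the glyoxylate cycle and non-fermentable carbon, 1 of 24 rose and 21 fell (1 and 21 adjusted over the list alone), and the isocitrate lyase gene ICL1 (1.98-fold) was the member that rose. For gluconeogenesis, the camera adjusted p was 1.06e-06, and the adjusted p was 0.533 with an estimated correlation. In the tricarboxylic acid cycle, 1 of 17 rose and 14 fell (1 and 15 adjusted over the list alone), with CIT3 (11-fold) and IDH2 (2.7-fold) the lowest. For the tricarboxylic acid cycle, the camera adjusted p was 8.69e-05, and the adjusted p was 0.533 with an estimated correlation. Mitochondrial ribosomal proteins, with 19 higher and 16 lower of 67, and translation factors, with 14 and 11 of 35, were not called (camera adjusted p = 0.594 and 0.737).

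Of the phosphate starvation genes, 1 of 20 rose and 16 fell (1 and 17 adjusted over the list alone), including GIT1 (3.92-fold), a transporter of glycerophosphoinositol. For phosphate genes, the camera adjusted p was 6.01e-04, and the adjusted p was 0.269 with an estimated correlation. Autophagy and vacuolar proteolysis genes fell, with LAP3 and ATG41 lowest at 4.11-fold and 5.17-fold below WT: 3 of 46 rose and 27 fell (3 and 27 adjusted over the list alone). For autophagy genes, the camera adjusted p was 6.74e-04, and the adjusted p was 0.264 with an estimated correlation. Of the general stress and storage carbohydrate genes, 5 of 34 rose and 19 fell (5 and 19 adjusted over the list alone), the glycogen synthase gene GSY2 (6.28-fold) and the trehalose gene TSL1 (3.95-fold) among those that fell. For stress and storage genes, the camera adjusted p was 0.00634, and the adjusted p was 0.533 with an estimated correlation. Mating genes rose, MFA2 (29.9-fold) and STE2 (9.04-fold), the α-factor receptor, most: 16 of 28 rose and 6 fell (16 and 6 adjusted over the list alone). For mating genes, the camera adjusted p was 3.65e-04, and the adjusted p was 0.264 with an estimated correlation. Of the methionine and sulfur genes, 14 of 25 rose and 6 fell (14 and 6 adjusted over the list alone), from MET17 (6.53-fold) higher to SAM3 (6.28-fold) lower. For methionine and sulfur genes, the camera adjusted p was 0.00632, and the adjusted p was 0.533 with an estimated correlation. For galactose and maltose use, 7 of 17 rose and 6 fell (7 and 6 adjusted over the list alone), and the list was called higher by the test and its mean of 1.22, while its median was -0.14. For galactose and maltose use, the camera adjusted p was 0.00632, and the adjusted p was 0.269 with an estimated correlation. GAL1 and GAL7 were lower, at 1.44 and 1.26 CPM against 4.69 and 4.62 CPM in WT.

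The lists closest to the known work of Pcf11 were not called. They hold levels of transcripts per gene, which do not measure 3' end processing or termination itself. Among the 3' end processing factors of the CPF-CF complexes, 5 of 21 rose and 8 fell (5 and 8 adjusted over the list alone), and camera gave an adjusted p of 0.825. Among the termination factors of the Nrd1-Nab3-Sen1, Rat1 and exosome list, 12 of 24 rose and 5 fell (12 and 5 adjusted over the list alone), and camera gave an adjusted p of 0.273. Among small nucleolar RNAs, whose ends depend on that pathway, 8 of 61 rose and 15 fell (4 and 10 adjusted over the list alone), and camera gave an adjusted p of 0.883. In all, edgeR called 1972 genes higher and 2033 lower of 6119 tested, 658 and 534 of them at least 2-fold. Camera called 10 of 35 gene lists, and 0 with an estimated correlation. Mapped shares and 5' UTR shares differed between the same libraries, as given above.

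Pcf11-AARR, in which conserved residues of Pcf11 are changed, differed from WT in many of the transcripts named for ΔPcf11. The maltose genes named for ΔPcf11 were again higher: MAL12 (293 ± 73.9 against 3.5 ± 0.382 CPM), MAL32 (189 ± 49.4 against 2.75 ± 0.545 CPM) and MAL11 (1039 ± 283 against 38.2 ± 4.12 CPM) (SD, n = 3). ASP3-2 and ASP3-4, with 2 and 3 reads in WT, stood at 6261 times (95% counting interval 1733 to 51700.0) and 615 times (95% counting interval 210.2 to 2984) the WT level. FAR1 (16.1-fold), which halts the cell cycle of mating cells, MFA2 (13.9-fold), ALD5 (12.9-fold), a mitochondrial aldehyde dehydrogenase gene, ERR3 (29.3-fold) and SNO4 (27.1-fold) rose too. ADY2 (385 ± 84.3 against 20756 ± 1929 CPM), ADH2 (146 ± 41.5 against 2912 ± 229 CPM), CIT3 (60.8 ± 7.29 against 2002 ± 88.2 CPM) and the formate dehydrogenase gene FDH2 (29.3 ± 8.19 against 1012 ± 231 CPM) fell. So did ENA1 (51.4-fold), ENA2 (84.9-fold) and PDR18 (134-fold). SEO1, AIF1, ADH7 and RDS1 were at 0.0685, 0.123, 0.159 and 0.121 CPM against 12.8, 15.5, 16.7 and 14.6 CPM in WT.

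Ribosome biogenesis genes rose in Pcf11-AARR as well: 77 of 97 rose and 5 fell (80 and 5 adjusted over the list alone), with NSR1 (6.92-fold) highest. For ribosome biogenesis, the camera adjusted p was 1.50e-08, and the adjusted p was 0.616 with an estimated correlation. Of the mitochondrial ribosomal proteins, 41 of 67 rose and 4 fell (42 and 4 adjusted over the list alone). For mitochondrial ribosomal proteins, the camera adjusted p was 0.00249, and the adjusted p was 0.769 with an estimated correlation. The cytosolic ones were not called, with 52 higher and 22 lower of 138 (camera adjusted p = 0.169). Termination and exosome genes rose: 16 of 24 rose and 4 fell (16 and 4 adjusted over the list alone), from TRF5 (4.34-fold) higher to PAP2 (4.08-fold) lower, both of which encode poly(A) polymerases of the nuclear exosome pathway. For termination and exosome genes, the camera adjusted p was 0.0279, and the adjusted p was 0.401 with an estimated correlation. Autophagy and vacuolar genes fell, ATG39 (2.93-fold) and CPS1 (3.46-fold) most: 1 of 46 rose and 30 fell (1 and 30 adjusted over the list alone). For autophagy genes, the camera adjusted p was 8.54e-06, and the adjusted p was 0.0516 with an estimated correlation. Of the tricarboxylic acid cycle genes, 1 of 17 rose and 14 fell (1 and 14 adjusted over the list alone). For the tricarboxylic acid cycle, the camera adjusted p was 0.00172, and the adjusted p was 0.542 with an estimated correlation. Of those for gluconeogenesis and non-fermentable carbon, 3 of 24 rose and 16 fell (3 and 16 adjusted over the list alone). For gluconeogenesis, the camera adjusted p was 0.00324, and the adjusted p was 0.769 with an estimated correlation. Stress and storage genes fell, GRE1 (6.44-fold) among the lowest: 6 of 34 rose and 22 fell (6 and 22 adjusted over the list alone). For stress and storage genes, the camera adjusted p was 0.00172, and the adjusted p was 0.542 with an estimated correlation. Mating genes rose: 16 of 28 rose and 8 fell (16 and 8 adjusted over the list alone). For mating genes, the camera adjusted p was 0.00172, and the adjusted p was 0.376 with an estimated correlation. Of the methionine and sulfur genes, 17 of 25 rose and 6 fell (17 and 6 adjusted over the list alone), MUP1 (6.28-fold) and MET17 (6.19-fold) among those that rose. For methionine and sulfur genes, the camera adjusted p was 0.00284, and the adjusted p was 0.401 with an estimated correlation. Galactose and maltose use was called higher with 8 genes higher and 8 lower of 17, 8 and 8 adjusted over the list alone, the GAL genes among those that fell. For galactose and maltose use, the camera adjusted p was 0.0274, and the adjusted p was 0.401 with an estimated correlation. Of the auxotrophic marker genes, 5 of 8 rose and 1 fell (5 and 1 adjusted over the list alone), with URA3 (504 ± 40.2 against 109.7 ± 4.49 CPM) and LEU2 (46.6 ± 9.69 against 14.7 ± 2.48 CPM). For marker genes, the camera adjusted p was 0.0452, and the adjusted p was 0.401 with an estimated correlation.

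EdgeR called 1986 genes higher and 2020 lower in Pcf11-AARR than in WT, 688 and 659 of them at least 2-fold, of 6119 tested. With the replicate number as a block, the counts were 1919 and 1956. Of 35 lists, camera called 11, and 0 with an estimated correlation. With the block 12 were called, these 11 and meiosis and sporulation, of which 9 rose and 17 fell of 34 (9 and 17 adjusted over the list alone). For this list the camera adjusted p was 0.0643 without the block and 0.0431 with it, and the adjusted p was 0.814 with an estimated correlation. The share of reads in 5' UTRs was 0.127% in these libraries and 0.49% in WT.

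Set against each other, Pcf11-AARR and the libraries labelled ΔPcf11 parted in glycolysis, ribosomal protein and phosphate genes. Glycolysis and ethanol formation genes were lower in Pcf11-AARR: 1 of 20 rose and 16 fell (1 and 16 adjusted over the list alone), with TDH1 (170.1 ± 42.3 against 549 ± 38.3 CPM) and PDC6 (46.2 ± 8.57 against 171 ± 9.93 CPM) lowest. For glycolysis, the camera adjusted p was 1.21e-07, and the adjusted p was 0.486 with an estimated correlation. Of the cytosolic ribosomal proteins, 2 of 138 rose and 75 fell (2 and 84 adjusted over the list alone). For cytosolic ribosomal proteins, the camera adjusted p was 9.45e-08, and the adjusted p was 0.571 with an estimated correlation. Of the mitochondrial ones, 36 of 67 rose and 3 fell (37 and 3 adjusted over the list alone). For mitochondrial ribosomal proteins, the camera adjusted p was 8.13e-06, and the adjusted p was 0.571 with an estimated correlation. Phosphate starvation genes were higher, GIT1 (2.92-fold) and PHO89 (2.64-fold) most: 14 of 20 rose and 2 fell (15 and 2 adjusted over the list alone). For phosphate genes, the camera adjusted p was 2.35e-06, and the adjusted p was 0.393 with an estimated correlation. Meiosis and sporulation genes were lower: 3 of 34 rose and 17 fell (3 and 19 adjusted over the list alone), led by IME1 (35.1 ± 5.34 against 199 ± 47.4 CPM), the master regulator of entry into meiosis, and SPO19 (7.12 ± 1.69 against 39.3 ± 9.82 CPM). For meiosis genes, the camera adjusted p was 2.59e-06, and the adjusted p was 0.486 with an estimated correlation.

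The single genes highest in Pcf11-AARR were CHA1 (115 ± 5.95 against 17.7 ± 10.9 CPM), TDA6 (10.4 ± 1.26 against 1.92 ± 0.168 CPM), HSP30 (939.6 ± 79.6 against 207 ± 6.13 CPM), a plasma membrane stress protein, and ROG3 (75.2 ± 14.7 against 19.2 ± 1.98 CPM), an arrestin-related gene. The mitochondrial intron gene AI1 averaged 21.5 ± 27.4 CPM against 1.89 ± 0.344, with a spread larger than its mean. The formate dehydrogenase genes FDH2 and FDH1, close paralogs, were 7.16-fold and 6.69-fold lower, and CIS1, 5.81-fold lower, is overlapped by YLR345W over 77.8% of its length. Of the chaperone genes, 14 of 28 rose and 2 fell (15 and 2 adjusted over the list alone), SSA4 (2.65-fold) and MDJ1 (2.29-fold) most. For chaperones, the camera adjusted p was 0.00214, and the adjusted p was 0.571 with an estimated correlation. Iron regulon genes rose, among them FTR1 (3.6-fold), the iron permease: 8 of 24 rose and 1 fell (9 and 2 adjusted over the list alone). For the iron regulon, the camera adjusted p was 0.0096, and the adjusted p was 0.639 with an estimated correlation. Of the amino acid biosynthesis genes, 18 of 45 rose and 4 fell (21 and 4 adjusted over the list alone). For amino acid biosynthesis, the camera adjusted p was 0.00953, and the adjusted p was 0.571 with an estimated correlation. Of those for gluconeogenesis, 10 of 24 rose and 3 fell (11 and 3 adjusted over the list alone). For gluconeogenesis, the camera adjusted p was 0.00735, and the adjusted p was 0.672 with an estimated correlation. Of ribosome biogenesis, 27 of 97 rose and 5 fell (15 and 3 adjusted over the list alone). For ribosome biogenesis, the camera adjusted p was 0.00991, and the adjusted p was 0.807 with an estimated correlation. Termination and exosome genes were again called higher: 9 of 24 rose and 1 fell (9 and 1 adjusted over the list alone). For termination and exosome genes, the camera adjusted p was 0.0459, and the adjusted p was 0.486 with an estimated correlation. Small nucleolar RNAs were lower: 2 of 61 rose and 19 fell (2 and 17 adjusted over the list alone). For small nucleolar RNAs, the camera adjusted p was 0.00524, and the adjusted p was 0.672 with an estimated correlation. Hexose transporters, with 9 of 21 lower and 1 higher (9 and 1 adjusted over the list alone), were called lower. So were thiamine genes, with 9 of 21 lower and 0 higher (9 and 0 adjusted over the list alone). The camera adjusted p was 0.0353 and 0.0246 for these lists, and the adjusted p was 0.486 for each with an estimated correlation. In all, 1368 genes were called higher and 1239 lower in Pcf11-AARR, 170 and 244 at least 2-fold, and camera called 14 of 35 lists, 0 with an estimated correlation.

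In the overexpression strains, many of the transcripts already named differed from WT once more. In Pcf11-OE1, MAL12 (546 ± 43.2 against 3.5 ± 0.396 CPM), MAL32 (353 ± 43.1 against 2.75 ± 0.554 CPM) and MAL11 (1781 ± 128 against 38.1 ± 4.29 CPM) were higher than in WT. In Pcf11-OE2 the 3 genes reached 706 ± 221, 475 ± 153 and 2219.7 ± 664 CPM (SD, n = 3). ASP3-2 and ASP3-4, with 2 and 3 reads in WT, stood at 5528 times (95% counting interval 1530.0 to 45649.9) and 984 times (95% counting interval 336 to 4772) the WT level in Pcf11-OE1. In Pcf11-OE2 they stood at 5839 times (95% counting interval 1616 to 48219) and 1043 times (95% counting interval 357 to 5062) it. FAR1 rose 21.5-fold and 18.2-fold in Pcf11-OE1 and Pcf11-OE2 and MFA2 25.5-fold and 36-fold. ERR3 rose 83.9-fold and 77.6-fold, SNO4 42.8-fold and 40.7-fold, and STE2 14.3-fold in Pcf11-OE2. Among transcripts that fell, ADY2 was at 229 ± 146 and 269 ± 223 CPM and RGI2, which is linked to respiratory growth, at 312 ± 204 and 392 ± 404 CPM, against 20747 and 13157 CPM in WT. PHO89 fell 74.8-fold and 75-fold and ENA1 35.8-fold and 30.5-fold. ENA2 fell 49.7-fold and 46.2-fold, and PDR18 158-fold and 167-fold. RDS1, AIF1, ADH7 and SEO1 were at or below 0.125 CPM in both strains.

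As groups, ribosome biogenesis genes rose and cytosolic ribosomal protein genes fell in both overexpression strains. Of the former, 69 of 97 rose and 4 fell (69 and 4 adjusted over the list alone) in Pcf11-OE1. For ribosome biogenesis, the camera adjusted p was 3.95e-05, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2, 56 of 97 rose and 4 fell (56 and 4 adjusted over the list alone). For ribosome biogenesis, the camera adjusted p was 0.00156, and the adjusted p was 0.871 with an estimated correlation. Of the latter, 21 of 138 rose and 67 fell (21 and 67 adjusted over the list alone) in Pcf11-OE1. For cytosolic ribosomal proteins, the camera adjusted p was 0.00552, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2, 21 of 138 rose and 70 fell (21 and 70 adjusted over the list alone). For cytosolic ribosomal proteins, the camera adjusted p was 0.00276, and the adjusted p was 0.871 with an estimated correlation. RPL11A was 4.87-fold and 5.37-fold lower in the 2 strains. Mitochondrial ribosomal proteins rose: 41 of 67 rose and 5 fell (41 and 5 adjusted over the list alone) in Pcf11-OE1. For mitochondrial ribosomal proteins, the camera adjusted p was 0.00659, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2, 44 of 67 rose and 4 fell (45 and 4 adjusted over the list alone). For mitochondrial ribosomal proteins, the camera adjusted p was 4.34e-04, and the adjusted p was 0.871 with an estimated correlation. Methionine and sulfur genes rose, MUP1, the methionine permease, 9.81-fold and 8.66-fold: 18 of 25 rose and 2 fell (19 and 2 adjusted over the list alone) in Pcf11-OE1. For methionine and sulfur genes, the camera adjusted p was 3.95e-05, and the adjusted p was 0.445 with an estimated correlation. In Pcf11-OE2, 18 of 25 rose and 2 fell (19 and 2 adjusted over the list alone). For methionine and sulfur genes, the camera adjusted p was 1.01e-04, and the adjusted p was 0.484 with an estimated correlation. Mating genes rose: 17 of 28 rose and 6 fell (17 and 6 adjusted over the list alone) in Pcf11-OE1. For mating genes, the camera adjusted p was 2.82e-04, and the adjusted p was 0.445 with an estimated correlation. In Pcf11-OE2, 18 of 28 rose and 5 fell (18 and 6 adjusted over the list alone). For mating genes, the camera adjusted p was 2.14e-05, and the adjusted p was 0.271 with an estimated correlation.

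Meiosis and sporulation genes fell, with IME1 10.03-fold and 8.3-fold below WT: 7 of 34 rose and 18 fell (7 and 18 adjusted over the list alone) in Pcf11-OE1. For meiosis genes, the camera adjusted p was 0.00525, and the adjusted p was 0.639 with an estimated correlation. In Pcf11-OE2, 7 of 34 rose and 16 fell (7 and 16 adjusted over the list alone). For meiosis genes, the camera adjusted p was 0.00777, and the adjusted p was 0.485 with an estimated correlation. Of the genes for gluconeogenesis and non-fermentable carbon, 2 of 24 rose and 19 fell (2 and 19 adjusted over the list alone) in Pcf11-OE1. For gluconeogenesis, the camera adjusted p was 0.00659, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2, 2 of 24 rose and 18 fell (2 and 18 adjusted over the list alone). For gluconeogenesis, the camera adjusted p was 0.00522, and the adjusted p was 0.871 with an estimated correlation. Of the autophagy and vacuolar genes, 3 of 46 rose and 31 fell (3 and 31 adjusted over the list alone) in Pcf11-OE1. For autophagy genes, the camera adjusted p was 7.88e-04, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2, 2 of 46 rose and 30 fell (2 and 30 adjusted over the list alone). For autophagy genes, the camera adjusted p was 0.00156, and the adjusted p was 0.871 with an estimated correlation. ATG17 was 3.72-fold and 3.46-fold lower. Galactose and maltose use was called higher in both, with 8 of 17 higher and 5 lower in each, as many adjusted over the list alone. The camera adjusted p was 0.025 and 0.0112, and the adjusted p was 0.639 and 0.484 with an estimated correlation. Auxotrophic marker genes were called higher, 6 of 8 rising and 1 falling in each strain, as many adjusted over the list alone. For these the camera adjusted p was 0.025 and 0.0418, and the adjusted p was 0.445 and 0.484 with an estimated correlation. URA3 stood at 304 ± 27.4 and 338 ± 40.7 CPM. Called lower in Pcf11-OE1 were also 3 further lists. Of the tricarboxylic acid cycle genes, 3 of 17 rose and 12 fell (3 and 13 adjusted over the list alone). For the tricarboxylic acid cycle, the camera adjusted p was 0.025, and the adjusted p was 0.892 with an estimated correlation. Of the oxidative phosphorylation genes, 4 of 37 rose and 20 fell (4 and 19 adjusted over the list alone). For oxidative phosphorylation, the camera adjusted p was 0.013, and the adjusted p was 0.892 with an estimated correlation. Of the stress and storage genes, 4 of 34 rose and 19 fell (4 and 19 adjusted over the list alone). For stress and storage genes, the camera adjusted p was 0.025, and the adjusted p was 0.892 with an estimated correlation. In Pcf11-OE2 these lists had camera adjusted p of 0.119, 0.177 and 0.0859.

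Of the genes that lend a promoter or terminator to the overexpression cassettes, CDC60 rose 2.59-fold in Pcf11-OE1 and 1.84-fold in Pcf11-OE2, TEF1 rose 1.49-fold and 1.41-fold, with reads that its copy TEF2 can share, and GRS1 and DIT1 fell in both. Against WT in the libraries labelled ΔPcf11 and in Pcf11-AARR, CDC60 rose 1.39-fold and 1.69-fold, TEF1 rose 1.51-fold and 1.38-fold, and GRS1 fell 1.66-fold and 1.39-fold, while DIT1 rose 1.58-fold in the former and fell 1.58-fold in the latter. Among 6119 tested genes, edgeR called 2162 higher and 2031 lower in Pcf11-OE1 than in WT, 810 and 763 at least 2-fold, and 2021 and 1957 in Pcf11-OE2, 682 and 672 at least 2-fold. Camera called 13 and 10 of 35 lists in Pcf11-OE1 and Pcf11-OE2, and 0 in either with an estimated correlation.

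**Figure D2:**
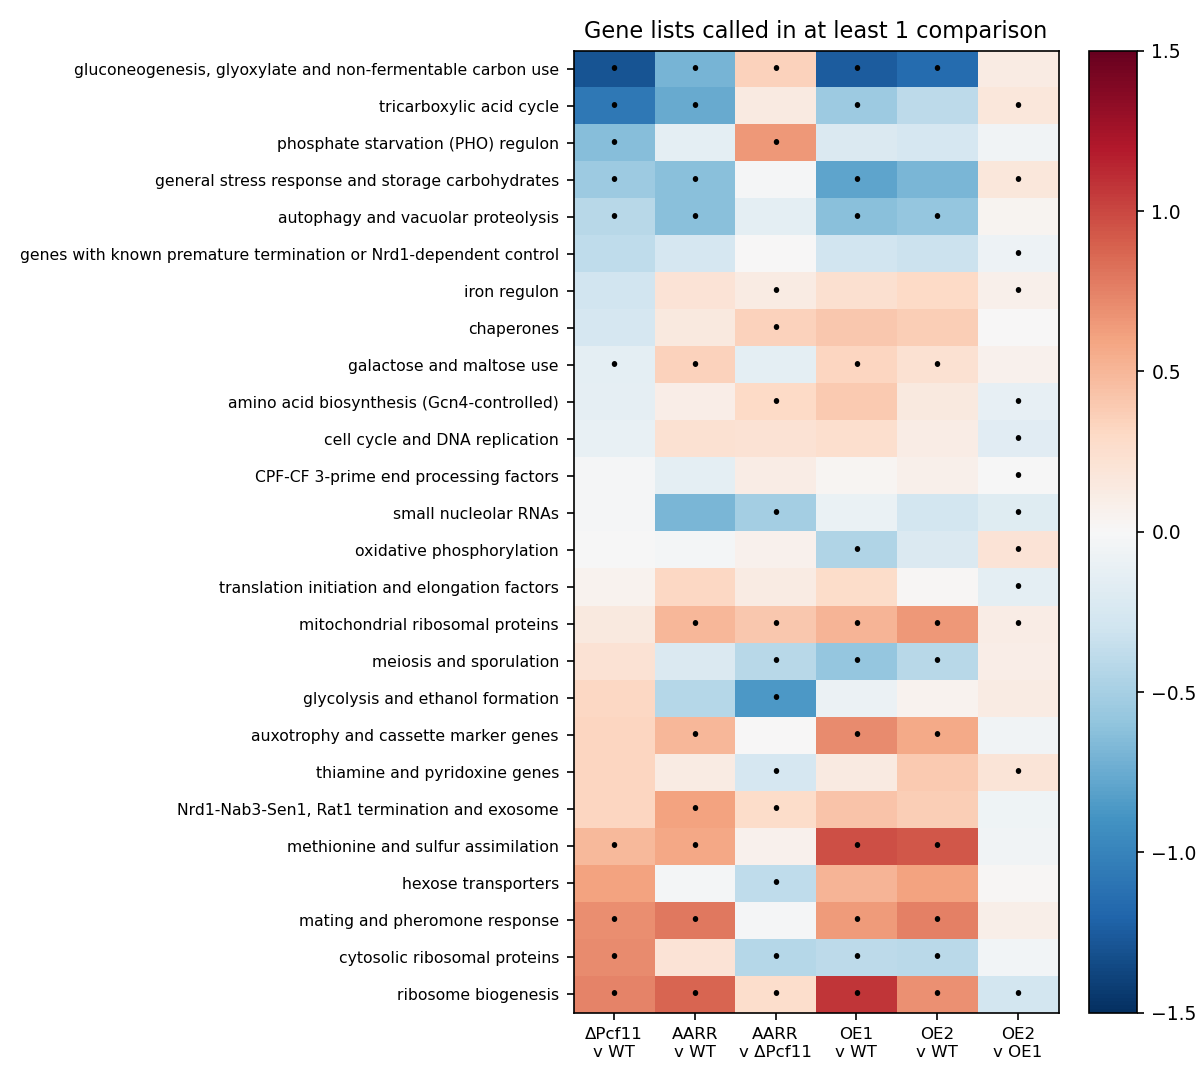
Median log2 fold change of each gene list called in at least 1 of the 6 comparisons, the color running from blue (lower in the group named first) to red (higher), with a dot where camera called the list with the preset correlation of 0.01. AARR, OE1 and OE2 stand for Pcf11-AARR, Pcf11-OE1 and Pcf11-OE2. Ribosome biogenesis is red with a dot in all 4 comparisons with WT, and gluconeogenesis blue with a dot.

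Between the overexpression strains, 14 genes were called higher and 76 lower in Pcf11-OE2, and 67 of the latter lie on chromosome I. Another split of the same libraries, which mixes the strains, gave 275 called genes. PCF11 was 7.74-fold lower in Pcf11-OE2 (edgeR adjusted p = 7.18e-06). Next came the chromosome I genes MAK16 (202 ± 67 against 595 ± 240.3 CPM), needed for the large ribosomal subunit, RBG1 (11.5 ± 3.04 against 30.1 ± 7.66 CPM), of which YAL037W overlaps 43%, FUN30 (27.9 ± 6.19 against 71.7 ± 13.4 CPM), a chromatin remodeler, and LTE1 (7.15 ± 0.473 against 17.4 ± 2.62 CPM), a mitotic exit gene. The median log2 fold change of Pcf11-OE1 over Pcf11-OE2 was 0.97 over 93 tested features of chromosome I, 90 of them above 0, against -0.0043 over the 6026 of the other chromosomes. Without chromosome I, an alternative chosen after seeing the data, 3 genes were called higher and 5 lower. Some of the genes named next as higher thus lost their call under it. Higher in Pcf11-OE2 were the iron genes FIT3 (62 ± 10.1 against 27.6 ± 3.63 CPM) and FIT2 (75.9 ± 11.2 against 36.9 ± 6.13 CPM), which encode cell wall mannoproteins that hold siderophore iron. So were TIS11 (235 ± 46.9 against 109.7 ± 8.07 CPM), an mRNA-binding regulator of iron use that SLX4 overlaps over 44.7%, THI5 (11.4 ± 2.46 against 6.08 ± 0.221 CPM), a thiamine synthesis gene with near-identical copies, and NCW2 (427 ± 76.9 against 231 ± 18.8 CPM), a cell wall gene.

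Camera called 13 lists between Pcf11-OE2 and Pcf11-OE1, most with few members that passed on their own. Called lower in Pcf11-OE2 were 7 lists. Of the ribosome biogenesis genes, 0 of 97 passed as higher and 1 as lower (0 and 1 adjusted over the list alone), median log2 fold change -0.27. For ribosome biogenesis, the camera adjusted p was 1.66e-06, and the adjusted p was 0.761 with an estimated correlation. Among cell cycle and DNA replication genes, 0 of 37 passed as higher and 3 as lower (0 and 6 adjusted over the list alone), median log2 fold change -0.17. For cell cycle genes, the camera adjusted p was 9.83e-07, and the adjusted p was 0.0891 with an estimated correlation. Of the translation factors, 0 of 35 passed as higher and 1 as lower (0 and 1 adjusted over the list alone), median log2 fold change -0.15. For translation factors, the camera adjusted p was 0.00353, and the adjusted p was 0.748 with an estimated correlation. For amino acid biosynthesis, 0 of 45 passed as higher and 1 as lower (0 and 1 adjusted over the list alone), median log2 fold change -0.12. For amino acid biosynthesis, the camera adjusted p was 0.018, and the adjusted p was 0.748 with an estimated correlation. Of the small nucleolar RNAs, 0 of 63 passed as higher and 1 as lower (0 and 1 adjusted over the list alone), median log2 fold change -0.18. For small nucleolar RNAs, the camera adjusted p was 0.0124, and the adjusted p was 0.536 with an estimated correlation. Of the genes known for premature termination, 1 of 15 passed as higher and 2 as lower (1 and 2 adjusted over the list alone), median log2 fold change -0.08. For premature termination genes, the camera adjusted p was 0.0051, and the adjusted p was 0.536 with an estimated correlation. The members lower were PCF11 itself and CLN3 on chromosome I, and the member higher was TIS11. Among CPF-CF factors, 0 of 21 passed as higher and 2 as lower (0 and 2 adjusted over the list alone), median log2 fold change -0.0044. For CPF-CF factors, the camera adjusted p was 0.00136, and the adjusted p was 0.329 with an estimated correlation. The members lower were PCF11 itself and PTA1 on chromosome I. PCF11 is the gene altered in these strains. Neither this list nor that of the premature termination genes was tested without it, so both calls may rest on PCF11.

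Called higher in Pcf11-OE2 were 6 lists. Of the iron regulon genes, 3 of 24 passed as higher and 0 as lower (4 and 0 adjusted over the list alone), median log2 fold change 0.07. For the iron regulon, the camera adjusted p was 0.00228, and the adjusted p was 0.723 with an estimated correlation. Among thiamine genes, 1 of 21 passed as higher and 0 as lower (6 and 0 adjusted over the list alone), median log2 fold change 0.20. For thiamine genes, the camera adjusted p was 7.74e-05, and the adjusted p was 0.339 with an estimated correlation. Of the oxidative phosphorylation genes, 0 of 37 passed as higher and 0 as lower (0 and 0 adjusted over the list alone), median log2 fold change 0.20. For oxidative phosphorylation, the camera adjusted p was 9.83e-07, and the adjusted p was 0.723 with an estimated correlation. In the tricarboxylic acid cycle, 0 of 17 passed as higher and 0 as lower (0 and 0 adjusted over the list alone), median log2 fold change 0.17. For the tricarboxylic acid cycle, the camera adjusted p was 0.00768, and the adjusted p was 0.748 with an estimated correlation. Of the mitochondrial ribosomal proteins, 0 of 67 passed as higher and 0 as lower (0 and 0 adjusted over the list alone), median log2 fold change 0.11. For mitochondrial ribosomal proteins, the camera adjusted p was 0.0123, and the adjusted p was 0.835 with an estimated correlation. Among stress and storage genes, 0 of 34 passed as higher and 0 as lower (0 and 0 adjusted over the list alone), median log2 fold change 0.17. For stress and storage genes, the camera adjusted p was 0.0231, and the adjusted p was 0.801 with an estimated correlation. With an estimated correlation camera called 0 lists. Of the 6119 genes, 580 had an unadjusted p below 0.05 in edgeR. The count of higher genes moved with the processing, from 3 without chromosome I to 50 with DESeq2, which brings its own scaling and filter, and without Pcf11-OE1 replicate 1, Pcf11-OE1 replicate 2 or Pcf11-OE2 replicate 3 it was 6, 8 and 6.

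**Figure D3:**
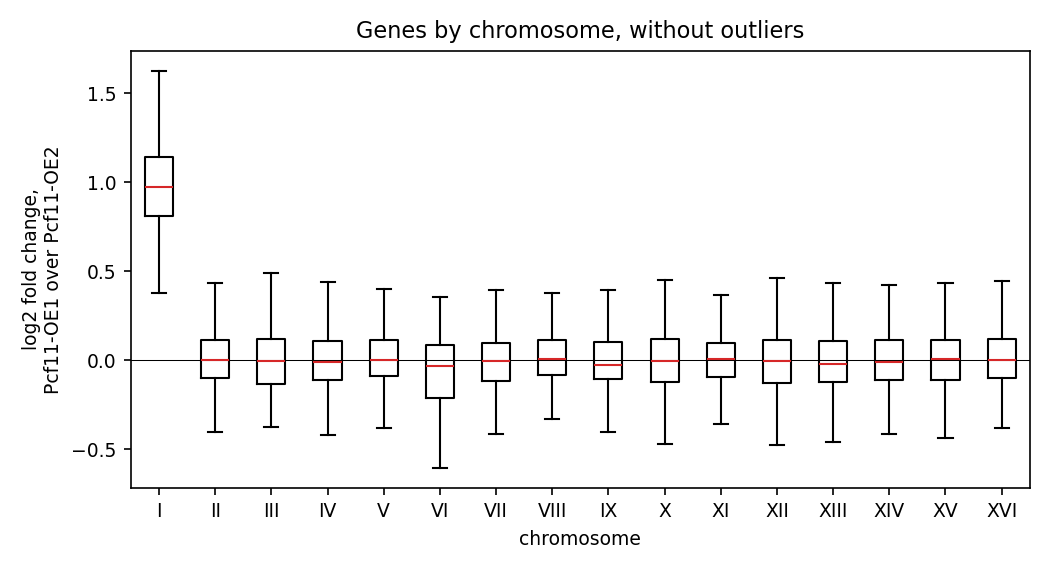
Log2 fold change of Pcf11-OE1 over Pcf11-OE2 for the tested genes of each nuclear chromosome, PCF11 left out. Boxes give the quartiles, red lines the medians and whiskers reach the farthest gene within 1.5 box lengths. The box of chromosome I spans 0.81 to 1.14, away from 0, around which those of the other chromosomes lie.

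Calls against WT were shared between strains labelled as lacking, changing or raising Pcf11. The libraries labelled ΔPcf11 and Pcf11-AARR shared 1413 genes called higher and 1500 called lower, where 640.0 and 671 would be shared if the calls were independent. In opposite directions 120 were called. The libraries labelled ΔPcf11 and Pcf11-OE1, at opposite ends by label, shared 1242 and 1201 (expected 695 and 677, 476 opposite). ΔPcf11 and Pcf11-OE2 shared 1206 and 1181 (expected 650.1 and 653, 410 opposite). Pcf11-OE1 and Pcf11-OE2 shared 1892 and 1810 (expected 714 and 649.6, 13 opposite). Across genes, which are not independent replicates, the log2 fold changes against WT correlated with a Pearson r of 0.861, 0.728, 0.751 and 0.976 for these pairs in this order, with covariances of 0.954, 0.868, 0.859 and 1.23. In simulated data with no change, groups that share the WT libraries gave a mean r of 0.498 to 0.509, covariances of 0.015 to 0.0178 and at most 1 shared call. Without changed genes almost none are called, so the simulated shared calls are no yardstick for the observed ones. Observed less simulated, the covariances were 0.939, 0.85, 0.842 and 1.22. The 3 WT libraries cannot be split between comparisons, so part of the excess of shared calls may come from the shared controls.

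**Figure D4:**
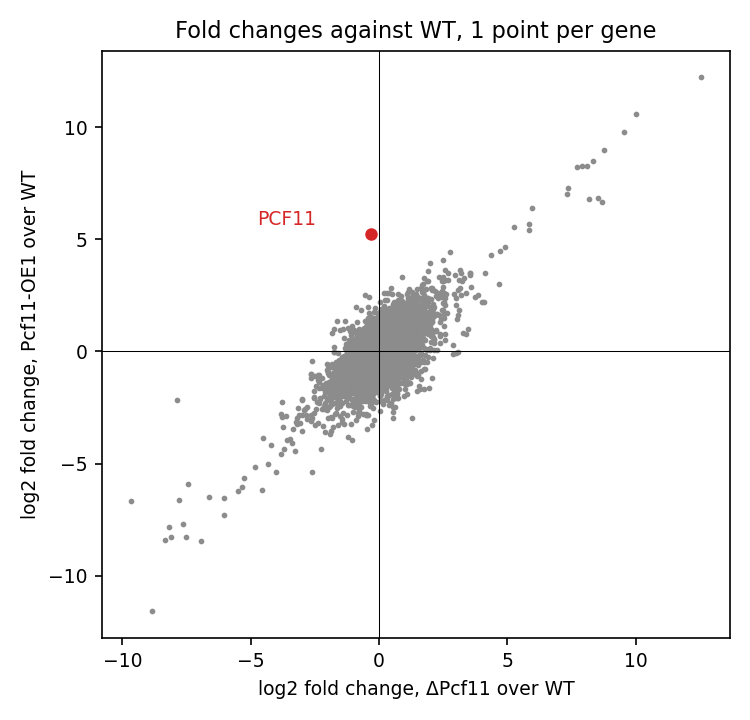
Log2 fold changes against WT of the libraries labelled ΔPcf11 (horizontal axis) and of Pcf11-OE1 (vertical axis), 1 point per gene, PCF11 in red. The genes far from 0 lie along the diagonal (Pearson r 0.728 across genes), and PCF11 lies off it at -0.30 and 5.26.

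Transcripts bound by Pcf11 were sought in the CLIP data. IP 1 had 1332 deposited peaks and IP 2 1707, with median lengths of 436.5 and 499 bases, and the inputs held 1104193 and 1034720 reads on genes. These peaks come from the authors' method ablife, with 317545 and 512533 reads after removal of duplicates. Their method piranha gave 323 and 477 peaks and their method cims 1617 and 2750, and results with these were not examined. The transcripts with the highest shared peaks were SPO24, ACH1, MLS1, CIT2, SED1, TMA10, QCR7, SDH1, POR1 and PYC1, with peak heights from 209 and 287 reads in IP 1 and IP 2 for SPO24 (chromosome XVI, bases 645875 to 646409) to 98 and 147 for PYC1. They encode, among others, acetyl-CoA hydrolase (ACH1), malate and citrate synthases of the glyoxylate cycle (MLS1, CIT2), respiratory chain subunits (QCR7, SDH1), the mitochondrial porin (POR1) and pyruvate carboxylase (PYC1). Each lay at or above percentile 98.8 of the input by FPKM, so that abundant RNAs lead the list. A sense peak in both IP libraries was found on 320 genes, where 157 would be found if the lists were independent, and the median input FPKM was 100.4 on these genes and 49.9 on the others. Beside 320 of 6428 features with an input value, 10 of 36 oxidative phosphorylation genes were bound, 8 of 35 translation factors, 22 of 136 cytosolic ribosomal proteins, 1 of 21 CPF-CF factors and 0 of 24 termination and exosome genes. The median input percentiles of these 5 lists were 98.8, 79.7, 79.3, 53.7 and 50.3, and bound shares of lists were not tested.

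Of the IP 1 peaks 28.5% overlapped a peak of IP 2 (380, 95% Wilson interval 26.17% to 31.01%), and of the IP 2 peaks 21.9% (374, 20.01% to 23.93%). On genes, 348 and 343 peaks were shared, where peaks placed at random in the same genes shared 294 and 295 on average and at most 321 and 319 in 100 placements. Most sense peaks had the largest part of their length in the coding sequence by the authors' annotation, 78.2% in IP 1 and 76.4% in IP 2, and 7.17% and 7.23% in the 3' UTR. In introns it was 13.5% and 15.1%. The SPO24 peak of IP 1 runs past both ends of the annotated gene and is given as 0.62 intron, so these region shares are uncertain. Midpoints of 42 of 230 shared peaks (18.3%) lay in the last of 5 equal parts of the open reading frame or within 250 bases after its stop, below the 37.4% of random midpoints (permutation p = 0.002, two-sided, the smallest that 1000 draws can give). With the summit in place of the midpoint, an alternative chosen after seeing the data, the share was 34.3% against 37.7% (permutation p = 0.308). Of the peaks placed by midpoint, 69.1% are longer than the distance from the middle to either end of the reading frame. A peak of that length lying within the frame cannot have its midpoint in the last of the 5 parts. The random midpoints did not take peak length into account. The low share of midpoints thus cannot be read as avoidance of the 3' end, and how far length lowers it was not tested. Fisher's exact tests called 0 of 4096 6-mers more or less frequent in the 291 shared peaks than in random windows of the same genes, with 53 below an unadjusted p of 0.05. Against shuffled peak sequence 87 were called more and 124 less frequent, and against random windows in the peaks of IP 1 or IP 2 alone 6 and 5 were called, all less frequent and led by TTTTTT and TTTTCT.

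**Figure D5:**
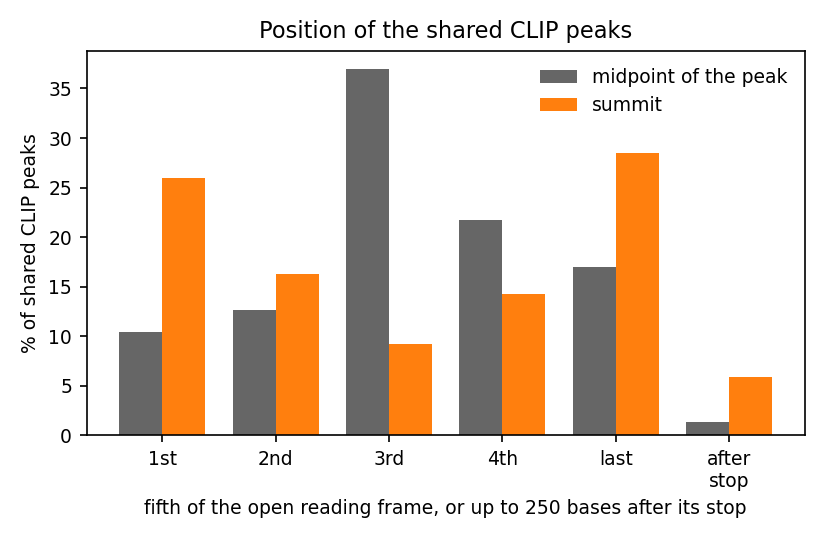
Percent of the shared CLIP peaks whose midpoint (grey) or summit (orange) lies in each of 5 equal parts of the open reading frame, from its start, or up to 250 bases after its stop. Of the midpoints, 85 of 230 lie in the middle part, and of the summits 22 of 239.

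The bound genes were then set against the expression changes. Of the 320 bound genes, 207 were called in the libraries labelled ΔPcf11 against WT, 64.7%, beside 65.5% of the others. The odds ratios over expression deciles were 0.925 for ΔPcf11, 1.01 for Pcf11-AARR, 0.888 for Pcf11-OE1 and 1.01 for Pcf11-OE2, each with an adjusted p of 1 in the exact Cochran-Mantel-Haenszel test. The 95% intervals of these ratios reach from 0.693 to 1.29. Taken by direction, the 320 bound genes did not pass either. For calls higher the odds ratios were 0.87, 0.917, 0.778 and 0.907 (exact test, adjusted p = 0.521, 0.521, 0.222 and 0.521) in the same order, and for calls lower the adjusted p was 0.671 in each. Without the deciles, calls higher passed in Pcf11-OE1 alone, with an odds ratio of 0.715 (exact test, adjusted p = 0.0326). In a subset, the 232 genes with peaks above the median height in both IP libraries, were the odds ratios for calls higher, 0.652, 0.704, 0.646 and 0.737, below an adjusted p of 0.05 (exact test, adjusted p = 0.0152, 0.0436, 0.0152 and 0.048). The test over deciles gave an unadjusted p below 0.05 in 10 of 100 random sets drawn by expression. Of the calls lower in this subset, those in Pcf11-AARR passed in the other direction, with an odds ratio of 1.44 (exact test, adjusted p = 0.0357), and the adjusted p was 0.0892 in each of the 3 others. Calls taken without regard to direction did not pass, with adjusted p of 0.693 to 0.943. Camera on the bound set gave adjusted p between 0.205 and 0.307 against WT. The inputs are labelled WT in their genotype and as Flag-Pcf11 overexpression in their description, and no CLIP library of untagged cells is among the labels.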

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

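Chosen only after the counts were seen was the look at features without a gene name, which the comparisons between strains do not describe. The table with Pcf11-AARR and ΔPcf11 holds 454 of these features and the table with Pcf11-OE1 and Pcf11-OE2 506, and 3 were at least 4-fold above every WT library and at 10 CPM or more in every Pcf11-AARR library, 7 in every library labelled ΔPcf11, 4 in every Pcf11-OE1 library and 4 in every Pcf11-OE2 library. Above every WT library in all 4 strains were 2 features. In the other direction, with every WT library at 10 CPM or more and at least 4-fold above every library of the strain, were 4 features for Pcf11-AARR, 4 for ΔPcf11, 6 for Pcf11-OE1 and 6 for Pcf11-OE2.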

How the results depend on the processing

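The alternatives without ribosomal RNA features, with features overlapping no other, without chromosome I, with all 5 groups in 1 fit, with the summit and with the peaks of 1 IP library were chosen only after the data were seen. Genes are given as higher and lower, in the order ΔPcf11 and Pcf11-AARR against WT, Pcf11-AARR against ΔPcf11, Pcf11-OE1 and Pcf11-OE2 against WT, and Pcf11-OE2 against Pcf11-OE1. Among features overlapping no other, 471 and 435, 487 and 441, 309 and 306, 529 and 465, 480 and 442, and 9 and 46 were called. At least 2-fold were 658 and 534, 688 and 659, 170 and 244, 810 and 763, 682 and 672, and 6 and 44, a subset by construction. At 2-fold, calls shared in the same direction numbered 417 and 364 for ΔPcf11 with Pcf11-AARR, 627 and 624 for Pcf11-OE1 with Pcf11-OE2, 350 and 303 for ΔPcf11 with Pcf11-OE1, and 327 and 288 for ΔPcf11 with Pcf11-OE2. With an estimated correlation camera called 0 lists in each of the 6 comparisons.

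The PCF11 log2 fold change of ΔPcf11 against WT was no longer called with relative log expression (-0.28), DESeq2 (-0.28), no filter (-0.26), only the 2 groups compared (-0.28), no ribosomal RNA features (-0.26), all 5 groups in 1 fit (-0.23) and the replicate block (-0.29), and leaving out 1 library gave -0.35 to -0.18. Genes higher in Pcf11-OE2 than in Pcf11-OE1 numbered 50 with DESeq2, which also changes scaling and filter, 7 at a mean CPM of at least 10, 7 with the replicate block, 5 with only the 2 groups compared and 3 without chromosome I, and 6 to 17 without 1 library (6 without Pcf11-OE1 replicate 1, 8 without Pcf11-OE1 replicate 2 and 6 without Pcf11-OE2 replicate 3). Lower ones numbered 5 without chromosome I, on which most of them lie, and 56 to 75 without 1 library. Leaving out 1 library gave 1703 to 1957 genes higher and 1690 to 1999 lower for ΔPcf11 against WT, and 1778 to 2082 and 1699 to 1926 for Pcf11-AARR. It gave 940 to 1410 and 893 to 1297 for Pcf11-AARR against ΔPcf11, 2010 to 2080 and 1824 to 1990 for Pcf11-OE1, and 1788 to 2091 and 1720 to 2005 for Pcf11-OE2. Among peaks above the median height, 37.4% of IP 1 and 28.6% of IP 2 were shared. The summit gave 34.3% near the 3' end. Against shuffled sequence 211 6-mers were called, and 6 and 5 in the peaks of IP 1 and IP 2 alone. Apart from the subsets and the lower calls that lie on chromosome I, the cause of these shifts was not tested. Of 14918 values of single genes and lists under the alternatives, 322 lost their call, 60 gained it and 0 turned direction. The single genes were those of the naming rule, mostly called genes with large changes, so few losses were likely from the choice. Of the lost calls, 71 were those of lists with an estimated correlation. Over all genes, 1812 of 2607 calls of Pcf11-AARR against ΔPcf11 stayed without ΔPcf11 replicate 3. For ΔPcf11 against WT, 3461 of 4005 did.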

Other observations

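The tests of strain background, of an effect graded with the PCF11 level, of diploid cells, of exchanged labels and of SIR4 reads, and the counts of other splits, were chosen only after the results were seen. Of 10 genes that haploid cells express, 8 were called lower in WT than in all 4 other strains, while STE18 was called higher in WT than in Pcf11-OE1 and Pcf11-OE2 and AXL1 higher in WT than in the libraries labelled ΔPcf11. Against 16.8 CPM in WT, RME1, a repressor of entry into meiosis, stood at 154 CPM in the libraries labelled ΔPcf11, 123 in Pcf11-AARR, 96 in Pcf11-OE1 and 118 in Pcf11-OE2, and FUS3, a kinase of the mating pathway, at 10.9 CPM in WT and 34.9 to 67.4 in the others. IME1, which starts meiosis, went the other way, with 899 CPM in WT and 35.1 to 199 in the others.

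In all 4 comparisons with WT, 53 genes were at least 8-fold apart in the same direction, 26 higher and 27 lower, and 0 of them were so in Pcf11-AARR against ΔPcf11 or in Pcf11-OE2 against Pcf11-OE1. Among all genes only 4 and 0 were that far apart there. Genes chosen for a like difference in all 4 strains are unlikely to be, so this 0 tells little. Log2 fold changes of Pcf11-OE2 rose with those of Pcf11-OE1 at a slope of 0.9401 ± 0.0029, where PCF11 itself gives 0.439. The SE is over 4455 genes, which are not independent. As a whole, the differences from WT were thus not graded with the PCF11 level of these strains. Both sets of fold changes rest on the same WT libraries, and a difference shared by both strains could hide a smaller graded effect. Such an effect, and one that saturates, stay open. A candidate explanation is that WT comes from another strain background: 16 pairs of these genes are neighbours, against at most 3 in 1000 random draws, and 14 against at most 6 among features that overlap no other. The 53 genes include clustered copies, such as ENA1, ENA2 and ENA5 and the ASP3 genes, which random draws of single genes do not mimic. The pairs can thus not be ascribed to the background alone. Cells of WT that are a/alpha diploids could lower 8 of 10 haploid-cell genes and 4 of 6 a-cell genes, as seen, but STE18, AXL1 and MFA1 were not lower in all 4 comparisons, AXL1 only in those with Pcf11-OE1 and Pcf11-OE2, and AGA2 was higher in WT in all 4, and this cannot be told apart from a change in mating signalling. Of the 53 genes, 27 (50.9%) lie within 30000 bases of a chromosome end, beside 6.43% of all tested genes. Silencing and growth state stay open and were not tested. Pcf11 itself stays open too, since every comparison with WT rests on the same 3 libraries.

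Transcripts of chromosome I were higher in Pcf11-OE1, by a median log2 fold change of 0.97 over Pcf11-OE2. GC content or gene length is argued against by a difference of 0.9888 from genes matched on both. An effect graded with the PCF11 level is argued against by a median of 0.09639 ± 0.146 (SE) for Pcf11-OE2 against WT over the other chromosomes, where 0.475 would be its part, although a threshold stays open. An extra copy of chromosome I in Pcf11-OE1 is consistent with the lowest median of its 3 parts, 0.8477, and with ratios to the other chromosomes of 2.06 to 2.15 in the Pcf11-OE1 libraries and 0.802 to 1.06 in the 12 others. DNA was not measured, so this remains a hypothesis.

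PCF11 counted 12.3 CPM in the libraries labelled ΔPcf11 and 15.1 CPM in WT, with any reads of SIR4 included. The lowest PCF11 level of any of the 15 libraries was 11.83 CPM. Reads of SIR4, if even and counted for PCF11 too, would give 7.76 CPM in the libraries labelled ΔPcf11 and 5.54 CPM in WT. Without that share, the level in the libraries labelled ΔPcf11 would lie further below WT than the counts show. A deletion need not bring the count near 0, so the lowest level of the 15 libraries cannot decide on an exchange of labels. A deletion that spares the part shared with SIR4 stays open. Reads of SIR4, on the other strand, could supply 63.11% of the PCF11 level in these libraries if SIR4 were read evenly, which leaves the source of the rest open. Whether the reading frame is present in part, or was changed without loss of the transcript, cannot be told apart from counts per gene. No biological explanation was tested.

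The 6 libraries of each comparison make 10 splits, too few for a share under 0.05. Genes called numbered 4005, 4006, 2607, 4193 and 3978 in the real splits of ΔPcf11 and Pcf11-AARR against WT, Pcf11-AARR against ΔPcf11, and Pcf11-OE1 and Pcf11-OE2 against WT, with 0 as the highest other in each, so 1 split of 10, the real one, gave as many. Each other split has libraries of both strains on each side, so differences between strains in many genes widen the spread within a side. The 0 was thus largely set in advance. For Pcf11-OE2 against Pcf11-OE1 the real split gave 90 and the highest other 275, with Pcf11-OE1 1, Pcf11-OE1 2 and Pcf11-OE2 2 on the same side, so 2 splits gave as many. A structure of the samples other than the strain may be involved, which was not tested. Lists called numbered 10, 11, 14, 13, 10 and 13, with 14, 14, 14, 14, 16 and 18 as the highest other, and 5, 5, 2, 2, 5 and 5 splits gave as many. The mixed splits keep part of the difference between strains, so their list counts are not a measure of false calls. Of the splits of Pcf11-AARR and WT, 4 part all 3 pairs, and the others of these gave 0 genes and at most 11 lists.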
